A study of Mus musculus with 10 samples.

How the data were processed

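RNA was measured in 10 libraries of endothelial cells purified from orthotopic gliomas in mice on a C57BL/6 background. Per the series' design text, cells of a mouse glioma line were injected into the brain. Per the same text, Sox7 or Sox17 was deleted in endothelium by crossing floxed alleles with the Cdh5(BAC)-CreERT2 line. In that line tamoxifen (20 mg/kg) activates a recombinase in endothelial cells. The sample labels give tamoxifen for the deficient samples only and leave the treatment of the controls unstated. Tamoxifen or recombinase activity may therefore go with the deletion in every comparison. Per the labels' protocols, RNA was extracted with Trizol and 500 ng of total RNA entered each library, made with the Lexogen QuantSeq kit, which reads a tag near the 3′ end of each polyadenylated transcript. The kit gives a count per transcript that does not grow with transcript length, and no molecular identifiers are mentioned in the labels. Floors given here therefore cover counting error only. Standard errors of fold changes and SDs over libraries also include the spread between libraries.

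The deposited values were whole-number counts per gene symbol, not normalised, 1 file per library. Bowtie2 and edgeR were named for alignment and analysis of mouse build mm10 per the submitters' processing notes, with no role, version or order; the annotation, the counting tool and its strand setting were not given in the sources used here. Symbols of multigene families (Hba and Hbb globins, H2 genes, ribosomal proteins with processed pseudogenes) are uncertain, since the counting could have split or shared their reads. The Sox7 files listed 23238 symbols and the Sox17 files 24421. The 1183 symbols found only in the Sox17 files all began with Mir and were left out, so that 23238 symbols entered the analysis. Repeated lines of a symbol (35 symbols in the Sox7 files, 43 in the Sox17 files) were summed. The row of the ribosomal RNA precursor, Rn45s, was kept, and an alternative left it out.

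Groups and replicate numbers came from the sample titles: 2 Sox7 control, 2 Sox7-deficient, 3 Sox17 control and 3 Sox17-deficient libraries. The design text speaks of independent sets, but the labels do not say that the libraries came from separate animals. The p-values therefore measure the spread between these samples, which may be partly technical. A deficient and a control library with the same number form a set. Shared run labels in the sample descriptions tie the members of 4 of the 5 sets, and Sox17 set 1 carries none, so the numbers were taken to pair the samples. As a check, the correlation of the paired libraries' deviations from their group means over genes was 0.2 in the Sox7 arm, where 2 libraries per group give both sets the same value, and 0.072, 0.062 and 0.053 in Sox17 sets 1, 2 and 3. All 6 Sox17 libraries lay closest to the other library of their own number.

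Counts were tested in R 4.3.3 with edgeR 4.0.16, by its quasi-likelihood F-test with robust dispersion estimates. All 10 libraries were fitted together with a mean per group, which left 6 residual degrees of freedom. Library sizes were scaled by TMM (trimmed mean of M-values), filterByExpr removed 10198 genes with few counts, and 13040 were tested. Adjusted p-values follow Benjamini and Hochberg over all genes tested in a comparison, with a threshold of 0.05. Standard errors of log2 fold changes were taken as the size of the fold change divided by the square root of F. The contrasts were Sox7-deficient against Sox7 control, Sox17-deficient against Sox17 control, and the first difference minus the second. CPM (counts-per-million) is relative to the TMM-scaled library size, given as mean ± SD over libraries. Differences per set are on the log2(CPM + 1) scale. Gene positions come from GENCODE vM21 on GRCm38, the assembly also called mm10.

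Gene lists were tested with camera in limma 3.58.1 on voom values of the same design, with a preset correlation of 0.01 between genes, adjusted over the 36 lists with 3 or more tested members. A second run estimated the correlation from the data, and fry tested whether the genes of a list moved, on balance, in 1 direction. The 40 lists covered the SoxF family, pan-endothelial genes, VEGF signalling, tip cells and tumour endothelium, the Notch pathway, arterial and venous endothelium, the blood-brain barrier, the Wnt/beta-catenin pathway and basement membrane. Further lists held shear-responsive genes, TGF-beta and BMP response, endothelial-to-mesenchymal transition, leukocyte adhesion, interferon response, antigen presentation, proliferation, hypoxia and glycolysis, cholesterol synthesis, p53 response, the unfolded protein response, immediate early genes, ribosomal proteins and mitochondrially encoded genes. Markers of other cells covered lymphatic endothelium, pericytes, smooth muscle, fibroblasts, macrophages, neutrophils, T and NK cells, B cells, dendritic cells, astrocytes, oligodendrocytes, neurons, glioma and neural progenitors, erythroid cells, choroid plexus and sex-linked genes. The mitochondrial and B cell lists had 0 tested members, the dendritic cell list 1 and the choroid plexus list 2, so these 4 lists were not tested. Several genes are members of more than 1 list. A further 24 myeloid and leukocyte genes outside these lists, of which 23 were tested, were written down after the data were seen and used only for a test of macrophage RNA.

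The groups, tests, gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined. Named genes were Sox7, Sox17 and Sox18, then up to 10 genes per direction past the threshold, with a mean of at least 5 CPM and the same direction in every set. Predicted genes and clones were left out. Where fewer than 5 genes qualified, genes past the threshold with the replicate block were taken, and then the 5 with the smallest p, named as not past the threshold. Up to 4 members of each list with the smallest p were also eligible. Any other gene that met the rule and is not named is not reported here. For the difference of effects the same rule applied without the condition on direction.

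Alternatives were median-of-ratios size factors, total counts without a scaling factor, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 5 CPM in at least 2 libraries, fits of only the compared groups, a replicate block for the set with 3 residual degrees of freedom, and leaving out each library in turn. Chosen after seeing the data were the fits without Rn45s, the replicate block with limma-voom or DESeq2, and lists without shared members and SoxF genes. With total counts the median log2 fold change of all genes moved by −0.114 in the Sox7 comparison and by −0.105 in the difference of effects. Other scalings moved it less. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

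The fit was tested on simulated data drawn from the real means and library sizes. At the spread of these data, with 12433 genes, 46.3% of genes changed by a log2 fold of 4 were recovered in the Sox7 comparison and 68.2% in the Sox17 comparison. At a log2 fold of 2 the shares were 5.97% and 16.7%, and at 1 they were 0% in both. The simulated Sox7 and Sox17 comparisons gave 6 and 4 false calls. With the replicate block they gave 26 and 15. The shares recovered with the block were 53.7% and 75.8% at a log2 fold of 4 and 7.46% and 18.2% at 2. No difference between sets was simulated, so the counts with the block need not hold for the real sets. Of 3 gene lists lowered by a log2 fold of 1, camera recovered 2 in each comparison with the preset correlation, and 0 (Sox7) and 1 (Sox17) with an estimated correlation, so that a call lost in that way does not show that a list was unchanged. Of the 33 other lists, 1 and 0 were called with the preset correlation. Genes were drawn independently of each other in these simulations. In the real Sox7 comparison the estimated correlation was 0.808 for macrophage genes and −0.00422 for Notch pathway genes. The simulated counts therefore do not cover false calls of lists whose members vary together. With low simulated noise and 12511 genes, 100% of the genes changed by a log2 fold of 2 were recovered in both comparisons.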

Results

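Endothelial cells purified from mouse orthotopic gliomas were profiled by 3′ tag sequencing after endothelial deletion of Sox7 or Sox17, transcription factors of the SoxF family that act in vascular development. There were 2 Sox7 control and 2 Sox7-deficient libraries, and 3 Sox17 control and 3 Sox17-deficient libraries. Each deficient library had a control of the same set number, and the Sox7 and Sox17 arms had separate controls. The sample labels give tamoxifen for deficient samples only, so differences may include effects of tamoxifen or recombinase activity. Total counts in the Sox7 arm were 9515034 in control 1, 9207072 in deficient 1, 9699934 in control 2 and 6781972 in deficient 2. In the Sox17 arm they were 2085020 and 6681760 in control and deficient 1, 11563564 and 35098704 in set 2, and 16815416 and 8178760 in set 3. Between 9735 and 15744 genes had a count. A floor of 3 counts corresponded to 0.086 CPM in the deepest library and 1.44 CPM in the shallowest. The ribosomal RNA precursor Rn45s took between 3.93% (Sox17-deficient 2) and 28.8% (Sox7-deficient 1) of the counts. Library correlations over genes were 0.713 to 0.881 within groups, 0.739 to 0.878 within sets and 0.685 to 0.932 between the other pairs, and the common biological coefficient of variation was 0.989.

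Each targeted transcript was reduced in its own deficient libraries and the other SoxF members showed no detectable change. Sox7 (GRCm38 chromosome 14, 63943673 to 63950732, plus strand, protein-coding) averaged 14.5 ± 12.2 CPM in controls (SD, n = 2) and 0.62 ± 0.061 CPM in Sox7-deficient libraries (n = 2), 4.28% of control. Its counts were 193 and 4 in set 1 and 64 and 5 in set 2. Sox17 (chromosome 1, 4490931 to 4497354, minus strand, protein-coding) averaged 119 ± 47.7 CPM in controls (n = 3) and 3.23 ± 3.03 CPM in Sox17-deficient libraries (n = 3), 2.71% of control. Its counts were 384 and 14, 1140 and 38, and 1508 and 54 in the 3 sets. The log2 fold change was −4.52 (SE 1.05) for Sox7 and −5.24 (SE 0.81) for Sox17, with edgeR adjusted p = 1 and 0.226 over all genes, and 0.00118 and 5.2e-05 adjusted over the list alone. With the replicate block the Sox17 change was −5.54 (edgeR adjusted p = 0.000897 over all genes). It also passed over all genes without Sox7-deficient 1 (adjusted p = 0.00381), Sox7-deficient 2 (0.00735) or Sox17-deficient 3 (0.0207), and with DESeq2 (9.05e-11). The Sox7 call over the list alone was lost with limma-voom (adjusted p = 0.329) and in a fit of only the Sox7 libraries (0.195). The labels do not give the floxed exons, so whether the 3′ tags lie in the deleted part is open. Wherever they lie, the tags were fewer than in the control of the set in every library labelled deficient for that gene. How the tags were lost was not tested.

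Sox17 in the Sox7 comparison had a log2 fold change of −0.14 (SE 0.82) and Sox18 (chromosome 2, 181669836 to 181671640, minus strand) of −0.90 (SE 1.13). Without Sox7 control 2 these were 0.59 and 1.42, and without Sox7-deficient 1 the Sox17 value was 0.57. In the Sox17 comparison Sox7 averaged 58.5 ± 41.4 CPM against 37.5 ± 22.2 in controls (log2 0.65, SE 0.70), and Sox18 had a log2 fold change of 0.50 (SE 0.91). Without Sox17-deficient 1 they were −0.02 and −0.14. All 4 values lay within the spread between replicates, with an edgeR adjusted p of 1.

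**Figure D1:**
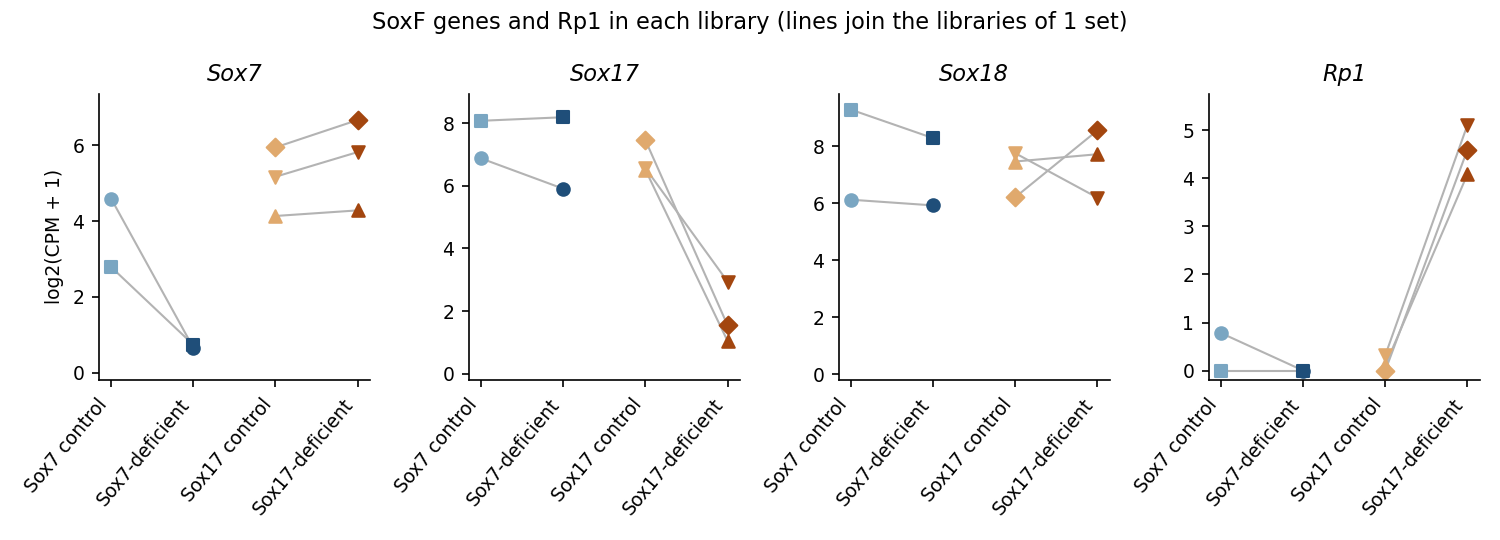
Expression of Sox7, Sox17, Sox18 and Rp1 in each library as log2(CPM + 1) on the y axis, with lines joining the control and deficient library of a set. Sox7 is lower in both Sox7-deficient libraries, Sox17 is lower in all 3 Sox17-deficient libraries, and Rp1 is high in the same 3 libraries.

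The Sox7 comparison asked which transcripts of glioma endothelium differ when Sox7 is deleted. Lists of endothelial identity, tip cell, Notch, arterial, venous, blood-brain barrier, basement membrane and immediate early genes fell in Sox7-deficient cells. Lists of ribosomal protein, antigen presentation and macrophage genes rose. The median log2 fold changes of these lists ran from −0.99 (arterial) to 1.5 (macrophage). In camera 11 of 36 lists passed, 3 higher and 8 lower. With an estimated correlation 0 passed (lowest adjusted p = 0.276), and fry gave 0 as well. Without Sox7-deficient 1 the count was 2, and none of the 11 kept its call in the same direction, since the macrophage list passed as lower. Without Sox7 control 1 the count was 3, with 2 of the 11 kept. With the replicate block 12 passed, adding the SoxF family (adjusted p = 0.0417, against 0.165 without the block), which was at adjusted p = 0.457 with the block and an estimated correlation. That list holds the deleted gene Sox7 itself (edgeR log2 −4.52), beside Sox17 (−0.14) and Sox18 (−0.90), so its pass says little about the family.

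No single gene passed the threshold with edgeR (0 of 13040), and 195 genes had an unadjusted p under 0.05, against 652 from chance alone. DESeq2 called 3 genes, limma-voom 0 and edgeR without a filter 58. The unadjusted count rose to 831 without Sox7-deficient 1, where 14 genes passed as lower, and to 784 without Sox7 control 1, where 3 passed as higher. One gene passed with the replicate block. For this comparison, in data simulated without differences between sets, that fit gave 26 false calls, against 6 without the block. The gene was Ms4a6c (chromosome 19, 11469366 to 11482192, plus strand), a membrane protein gene of the myeloid Ms4a cluster. It was at 270 ± 370 CPM against 11.5 ± 16.2 in controls, with a log2 fold change of 5.01 with the block (edgeR adjusted p = 0.0247). Without the block it was 4.55 (SE 2.69, adjusted p = 1), and without Sox7-deficient 1 it was −0.52.

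Other genes with the smallest p and the same direction in both sets were all at adjusted p = 1 with edgeR. In set 1 the deficient library also held more macrophage transcripts (geometric mean 345.4 against 22.0 CPM + 1 in its control). Unc93b1, which carries Toll-like receptors to endosomes, had 249 ± 262 CPM against 40.2 ± 18.7 (log2 2.63, SE 0.73). The lysosomal protease gene Ctsd had a log2 difference of 2.11 (SE 0.66), with 2.76 in set 1 and 0.26 in set 2. The glycoprotein gene Lgals3bp differed by 2.30 (SE 0.72), the adaptor subunit gene Ap1b1 by 1.72 (SE 0.52; 158 ± 56.2 against 48.1 ± 8.84 CPM) and the cytokine gene Mif by 1.81 (SE 0.60; 124 ± 6.55 against 35.4 ± 28.5 CPM). On the lower side were Cyp26b1, a retinoic acid hydroxylase, at 28.8 ± 2.7 against 142 ± 84.8 CPM (log2 −2.31, SE 0.68), and the water channel gene Aqp1 (−4.80, SE 1.48). Ccdc85a (−4.32, SE 1.28) and Dcaf5 (−1.94, SE 0.64) were also lower. Unc93b1 (0.0123) and Lgals3bp (0.0387) passed without a filter on low counts, and Aqp1 (0.0139) and Lgals3bp (0.0219) with DESeq2 and the replicate block, as adjusted p.

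Genes of general endothelial identity fell together. Of 22 pan-endothelial genes 20 were lower, with a median of −0.51 (camera adjusted p = 0.000518; adjusted p = 0.397 with an estimated correlation). Vwf, the von Willebrand factor of endothelial storage granules, was at −0.97 (SE 0.56), Mmrn2 at −0.72 (SE 0.47), the adhesion molecule gene Icam2 at −0.67 (SE 0.45) and Adgrf5 at −0.68 (SE 0.46). Tip cell and tumour endothelium genes had a median of −0.64, with 15 of 18 lower (adjusted p = 0.00315; adjusted p = 0.276 with an estimated correlation), among them the guidance receptor gene Unc5b (−1.16, SE 0.59). Basement membrane genes had a median of −0.46, with 14 of 15 lower (adjusted p = 0.00315; adjusted p = 0.397 with an estimated correlation). The collagen IV gene Col4a1 was at −0.86 (SE 0.45) and the nidogen gene Nid2 at −0.97 (SE 0.61). No member of these lists passed adjusted over the list alone. The geometric mean of the pan-endothelial genes was 509.6 and 285.5 in control and deficient of set 1 and 496.4 and 453.1 in set 2, as CPM + 1. All 3 lists lost their call without Sox7-deficient 1 (adjusted p = 0.743, 0.422 and 0.619 for pan-endothelial, tip cell and basement membrane). The mean of the tip cell list was then −0.534, against −0.521 with all libraries, while the pan-endothelial mean was −0.176 against −0.48 and the basement membrane mean −0.268 against −0.49. In set 2 the mean differences were −0.402 (SE 0.237) for tip cell, −0.132 (SE 0.109) for pan-endothelial and −0.205 (SE 0.129) for basement membrane genes. Without Sox7 control 1 the tip cell mean was −0.454 and the basement membrane mean −0.483, and both calls were lost. Without shared members and SoxF genes the tip cell list was at 0.175, with a mean of −0.375. Macrophage genes had a geometric mean of 345.4 CPM + 1 in Sox7-deficient 1, against 22.0 in its control.

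Notch, arterial and venous genes fell as groups. Notch pathway genes had a median of −0.60, with 10 of 15 lower (adjusted p = 0.00724; adjusted p = 0.276 with an estimated correlation). Nrarp, a Notch target and feedback inhibitor, was at 128 ± 11.6 CPM against 257 ± 59 (log2 −1.01, SE 0.48), and the ligand genes Dll4 and Jag1 were at −0.81 (SE 0.55) and −1.04 (SE 0.63). Arterial genes had a median of −0.99, with 12 of 16 lower (adjusted p = 0.00734; adjusted p = 0.397 with an estimated correlation). The gap junction gene Gja4 was at −1.43 (SE 0.70) and the lymphangiogenic growth factor gene Vegfc at −3.05 (SE 1.53). The mean arterial difference was −1.43 in set 1 and −0.29 in set 2. Venous genes had a median of −0.57, with 11 of 13 lower (adjusted p = 0.0107; adjusted p = 0.397 with an estimated correlation), including the P-selectin gene Selp (−2.11, SE 1.02). Mean differences in set 2 were −0.539 (SE 0.317) for Notch and −0.495 (SE 0.178) for venous genes. Without Sox7-deficient 1 the adjusted p was 0.353 for Notch and 0.547 for both arterial and venous genes, but the means were −0.441, −1.26 and −0.497, against −0.378, −1.15 and −0.627 with all libraries. Without Sox7 control 1 it was 0.0501, 0.306 and 0.0501, with means of −0.386, −0.462 and −0.702, so that the arterial mean shrank. Without Sox7 control 2 it was 0.06 for Notch (mean −0.396) and 0.134 for venous genes (mean −0.589). Without shared members and SoxF genes the arterial (0.448, mean −1.02) and venous (0.0795, mean −0.483) calls were lost. Sox7-deficient 1 is also the library with high macrophage transcripts (geometric mean 345.4 against 22.0 CPM + 1 in its control).

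Barrier and immediate early genes fell as well. The blood-brain barrier list had a median of −0.38, with 16 of 20 lower (adjusted p = 0.00693; adjusted p = 0.641 with an estimated correlation). The monocarboxylate transporter gene Slc16a1 was at −1.09 (SE 0.57) and the glucose transporter gene Slc2a1 at −0.92 (SE 0.65; 0.48 without Sox7 control 2). The list mean was −0.84 in set 1 and 0.03 in set 2, and it was 0.109 in the fit without Sox7-deficient 1. Without Sox7 control 2 its adjusted p was 0.259. Immediate early genes, which respond within minutes to stimuli including tissue dissociation, had a median of −0.60, with 15 of 16 lower (adjusted p = 0.00143; adjusted p = 0.397 with an estimated correlation). Nr4a1 was at −0.89 (SE 0.53) and Jun at −0.75 (SE 0.57). This call was lost without Sox7 control 1 and without Sox7-deficient 1. The list mean was −0.435 and −0.609 in these fits, against −0.578 with all libraries. In set 2 it was −0.416 (SE 0.102). Sox7-deficient 1 was also the library with high macrophage transcripts (345.4 against 22.0 CPM + 1).

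Macrophage markers, which the endothelial purification would be meant to deplete, were much higher in 1 of the 2 Sox7-deficient libraries. All 17 tested macrophage genes were higher in the fit, with a median of 1.5 (adjusted p = 0.0311; adjusted p = 0.87 with an estimated correlation), but the mean difference was 3.97 in set 1 and −1.13 in set 2. Their geometric mean was 22.0 and 345.4 CPM + 1 in control and deficient of set 1, and 9.0 and 4.1 in set 2. The receptor gene Csf1r had a log2 fold change of 4.06 (SE 1.96) and the lysosomal gene Cd68 of 4.92 (SE 2.21). All 13 antigen presentation genes were higher, with a median of 0.54 (adjusted p = 0.0179; adjusted p = 0.641 with an estimated correlation), led by the MHC class II gene H2-Eb1 (2.84, SE 0.98) and by Cd74, the invariant chain gene (2.16, SE 0.78). Their mean difference was 1.33 in set 1 and −0.18 in set 2. Ribosomal protein genes had a median of 0.29, with 67 of 75 higher (adjusted p = 0.00168; adjusted p = 0.662 with an estimated correlation). Rpl36 was at 0.97 (SE 0.52), and the list mean was 0.66 in set 1 and −0.02 in set 2. Without Sox7-deficient 1 the macrophage list reversed to −2.70 (adjusted p = 0.0351) and the antigen presentation list to −0.72, as did Csf1r (−1.22) and Cd74 (−0.40), and the ribosomal list was at 0.627 (mean 0.0112). Without Sox7 control 1 the macrophage, antigen presentation and ribosomal lists were at 0.0635, 0.0792 and 0.489, with means of 2.23, 0.647 and 0.235. Without Sox7 control 2 the macrophage list was at 0.371 (mean 0.0737) and the antigen presentation list at 0.0879 (mean 0.192), against means of 1.16 and 0.441 with all libraries.

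**Figure D2:**
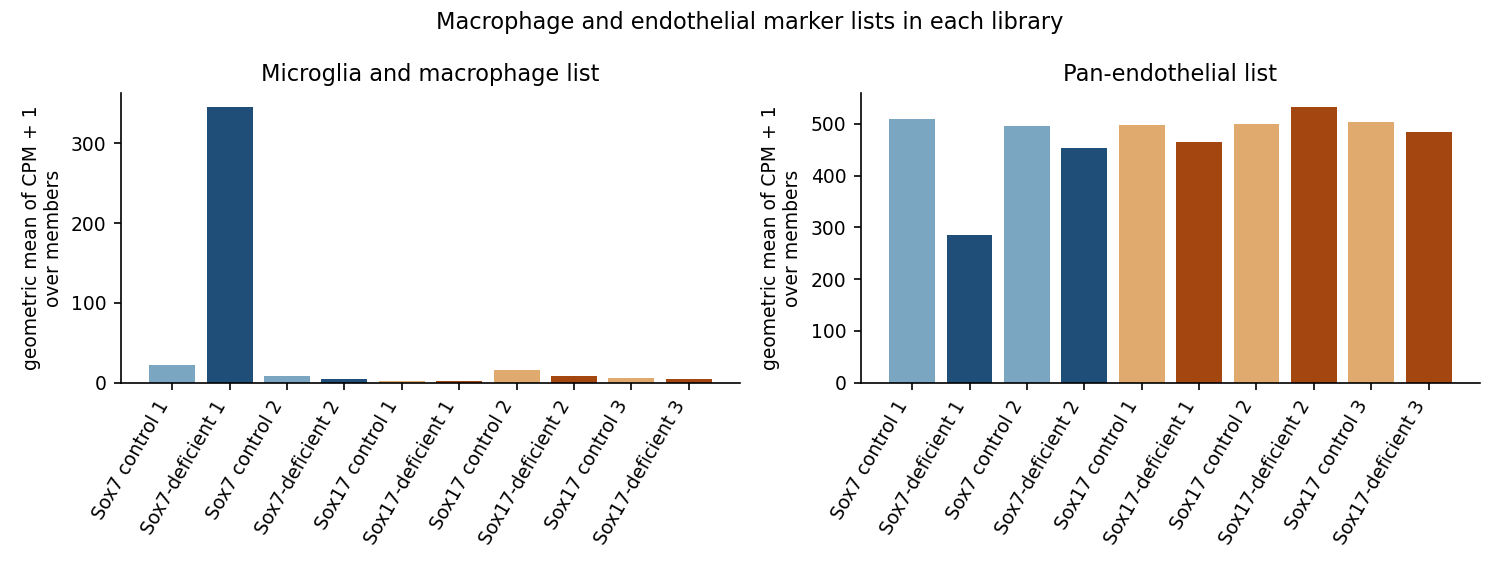
Geometric mean of CPM + 1 over the macrophage list and over the pan-endothelial list in each of the 10 libraries, as bars from 0. The macrophage list is at 345.4 in Sox7-deficient 1 and at 22.0 or less in the other 9 libraries.

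Some named genes of lists that did not pass are given by value. The glycolytic hexokinase gene Hk2 was at 3.84 (SE 1.56), with 3.78 in set 1 and 3.42 in set 2. Its adjusted p was 1 with edgeR, 0.000177 without a filter and 0.000951 with DESeq2 and the replicate block. The chemokine gene Cxcl1 was at −1.86 (SE 0.65) and the matrix protein gene Tgfbi at 2.44 (SE 0.88), with 3.40 in set 1, where the deficient library held more macrophage transcripts (345.4 against 22.0 CPM + 1), and 0.23 in set 2. The VEGF receptor gene Kdr, chosen after its values were seen, was at −0.30 (SE 0.48).

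The Sox17 comparison asked the same of Sox17 loss. Blood-brain barrier, arterial, pericyte and erythroid lists fell in Sox17-deficient cells. Ribosomal protein, proliferation, venous, hypoxia and basement membrane lists rose. Median log2 fold changes ran from −1.69 (erythroid) to 0.71 (proliferation), and the pan-endothelial list had a median of −0.01, with 11 members higher and 11 lower. In camera 9 of 36 lists passed, 5 higher and 4 lower, and 15 passed with the replicate block, all 9 among them. With an estimated correlation 0 passed (lowest adjusted p = 0.375), and fry gave 0 as well. Leaving out Sox17 control 2 gave 6 lists.

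No single gene passed the threshold with edgeR (0 of 13040; smallest adjusted p = 0.226, Sox17 itself), with 459 genes at an unadjusted p under 0.05 against 652 from chance alone. DESeq2 called 29 genes, limma-voom 0 and edgeR without a filter 30. With the replicate block 6 genes passed, 1 higher and 5 lower. For this comparison, in data simulated without differences between sets, that fit gave 15 false calls, against 4 without the block. The higher gene was Lrg1 (chromosome 17, 56119678 to 56122001, minus strand), which encodes a secreted glycoprotein of venous endothelium that promotes angiogenesis. It was at 685 ± 113 CPM in deficient libraries against 171 ± 153 in controls (log2 1.99, SE 0.65; adjusted p = 0.0233 with the block), with differences of 3.36, 2.75 and 1.03 in the 3 sets. Besides Sox17, the lower genes included Slc16a1 (chromosome 3, 104638668 to 104658462, plus strand), a lactate and ketone transporter of brain capillaries, at 99.8 ± 33.7 against 400 ± 90.8 CPM (log2 −2.0, SE 0.48; adjusted p = 0.0157 with the block). The aromatic amino acid decarboxylase gene Ddc (chromosome 11, 11814101 to 11898144, minus strand) was at 43.9 ± 28.6 against 179 ± 88.6 CPM (log2 −2.02, SE 0.61; adjusted p = 0.0157 with the block). Cd72 (0 counts in the deficient libraries, 2.98 ± 3.99 CPM in controls; adjusted p = 0.00767) and Ms4a6c (log2 −4.68, adjusted p = 0.023) also passed with the block. Among the controls Cd72 and Ms4a6c were highest in control 2 (7.51 and 18.7 CPM). Neither fell in set 1, where Cd72 had 0 CPM in both libraries and Ms4a6c 0 in control and 0.138 CPM in deficient. Both lay outside the naming rule and were chosen after their values were seen.

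Other genes with the smallest p and the same direction in all 3 sets had adjusted p = 1 with edgeR. The imprinted non-coding RNA gene H19 was at 72.3 CPM against 1.46 in controls (log2 5.49, SE 1.24), with 6.97, 0.92 and 3.28 in the 3 sets, and DESeq2 called it (adjusted p = 0.000158). The calcium-binding protein gene S100a6 differed by 1.55 (SE 0.44), Tnfaip2 by 1.55 (SE 0.48) and Ciapin1 by 1.32 (SE 0.41). Lower values were seen for Rgs5, a regulator of G-protein signalling typical of pericytes (chromosome 1, 169655501 to 169695813, plus strand), at 66.6 ± 23.1 against 321 ± 280 CPM (log2 −2.27, SE 0.60; DESeq2 adjusted p = 0.0465). Efr3b was at −1.85 (SE 0.50) and Gltscr1l at −1.95 (SE 0.53).

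Rp1, a microtubule-associated gene best known from photoreceptors, was almost absent from controls and present in every Sox17-deficient library. It lies on chromosome 1 (3999557 to 4409241, minus strand), 81689 bp downstream of Sox17 on the same strand. Its counts were 0, 1 and 4 in Sox17 controls and 169, 568 and 271 in the deficient libraries, or 0.109 ± 0.127 against 24.3 ± 8.84 CPM. The log2 fold change was 7.38 (SE 2.14; adjusted p = 1 with edgeR, 0.0021 with DESeq2). In the Sox7 arm the counts were 6 in Sox7 control 1 and 0 in the other 3 libraries.

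Blood-brain barrier genes fell in all 3 sets, with mean differences of −0.67, −0.77 and −0.38. Of 20 genes 18 were lower, with a median of −0.56 (adjusted p = 0.000489; adjusted p = 0.375 with an estimated correlation). Besides Slc16a1 the extracellular proteoglycan gene Spock2 was at −1.91 (SE 0.57), and these 2 genes passed adjusted over the list alone. The lipid transporter gene Mfsd2a was at −0.99 (SE 0.48) and the amino acid transporter gene Slc7a5 at −0.83 (SE 0.41). Arterial genes fell in all 3 sets as well, by means of −0.64, −1.12 and −0.46. Of 16 genes 14 were lower, with a median of −0.98 (adjusted p = 0.000489; adjusted p = 0.375 with an estimated correlation). The chemokine gene Cxcl12 was at 580 ± 146 against 2160 ± 1730 CPM (log2 −1.90, SE 0.57), the Notch target gene Hey1 at −1.74 (SE 0.73) and Unc5b at −1.12 (SE 0.48). Neither list lost its call when any of the 10 libraries was left out, with a highest adjusted p of 0.0242 for barrier and 0.0294 for arterial genes.

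Mural and blood cell markers were lower in the same libraries. Pericyte genes had a median of −1.0, with 10 of 11 lower (adjusted p = 0.00398; adjusted p = 0.411 with an estimated correlation), and Rgs5 passed adjusted over the list alone. Atp13a5 was at −1.84 (SE 0.84) and the PDGF receptor gene Pdgfrb at −0.98 (SE 0.66). Without Sox17 control 2 the pericyte list was at 0.478, and its mean was −0.285 against −0.943 with all libraries. All 5 erythroid genes were lower, with a median of −1.69 (adjusted p = 0.000791; adjusted p = 0.375 with an estimated correlation). The beta globin genes Hbb-bt and Hbb-bs, whose reads the counting could have split or shared, were at −2.92 (SE 1.22) and −2.23 (SE 1.08). Without Sox17-deficient 2 the erythroid list was at 0.256, and its mean was −0.869 against −2.22 with all libraries.

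Proliferation and ribosomal protein genes rose. Of 21 proliferation genes 19 were higher, with a median of 0.71 (adjusted p = 0.000489; adjusted p = 0.375 with an estimated correlation) and mean differences of 2.21, 0.74 and −0.10 in the 3 sets. The cell cycle kinase gene Cdk1 was at 165 CPM against 68.5 (log2 1.27, SE 0.44), Plk1 at 1.20 (SE 0.73) and Birc5 at 0.83 (SE 0.53). Ribosomal protein genes had a median of 0.39, with 67 of 75 higher (adjusted p = 1.98e-11; adjusted p = 0.375 with an estimated correlation) and means of 1.08, 0.50 and −0.000851 in the 3 sets. Rps2 was at 1.40 (SE 0.50) and Rps3 at 1.06 (SE 0.49). Both lists kept their call without any of the 10 libraries. In sets 1 and 2 the deficient library had more total counts than its control (6681760 against 2085020, and 35098704 against 11563564). In set 3, where neither list rose, it had fewer (8178760 against 16815416). The rise of both lists therefore went with depth over the 3 sets. Leaving out 1 library does not separate depth from Sox17 loss. Hypoxia and glycolysis genes had a median of 0.39, with 16 of 18 higher (adjusted p = 0.0204; adjusted p = 0.375 with an estimated correlation). Their mean differences were 1.05, 0.351 and −0.00787 in the 3 sets. Pfkfb3 was at 0.43 (SE 0.37) and Ldha at 0.39 (SE 0.36). The hypoxia call was lost without Sox17-deficient 1 (0.14, mean 0.362), Sox17-deficient 2 (0.178, mean 0.541) or Sox17 control 3 (0.105, mean 0.741), against a mean of 0.559 with all libraries.

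Venous genes rose, with a median of 0.27 and 11 of 13 higher (adjusted p = 0.0108; adjusted p = 0.375 with an estimated correlation). Their mean differences were 1.48 (SE 0.595), 0.771 (SE 0.238) and 0.0316 (SE 0.156) in sets 1, 2 and 3, so set 3 showed no clear rise. After Lrg1, the chemokine-scavenging receptor gene Ackr1 had the next smallest p, at 618 CPM against 240 (log2 1.37, SE 0.54), and Vwf was at 0.69 (SE 0.45). Basement membrane genes had a median of 0.145, with 11 of 15 higher (adjusted p = 0.029; adjusted p = 0.411 with an estimated correlation). The collagen XVIII gene Col18a1 was at 1.08 (SE 0.50) and the laminin gene Lamc1 at 0.76 (SE 0.39). The venous call was lost without Sox17 control 2 (0.337), where the mean was 0.216 against 0.545 with all libraries, or without Sox17-deficient 3 (0.0559, mean 0.503). The basement membrane mean was 0.242. Its call was lost without Sox17 control 2 (0.403, mean 0.105), Sox17-deficient 2 (0.106, mean 0.261) or Sox17-deficient 3 (0.208, mean 0.19). It was also lost without shared members and SoxF genes (0.16, mean 0.209).

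With the replicate block 6 further lists passed in the Sox17 comparison. The tip cell list (adjusted p = 0.0333, against 0.123 without the block) and the TGF-beta list (0.0229 against 0.137) were higher. Wnt/beta-catenin (0.00601 against 0.165), macrophage (0.0171 against 0.2), neutrophil (0.0491 against 0.406) and astrocyte lists (0.0193 against 0.165) were lower. With the block and an estimated correlation none of the 36 lists passed, with an adjusted p of 0.655 for macrophages and 0.538 for the other 5. Without the block the tip cell list also passed without Sox17 control 1 (0.0441), the Wnt list without Sox17-deficient 1 (0.0492) or Sox17 control 3 (0.004), and the macrophage list without Sox17-deficient 2 (0.00921). Among their members, the angiopoietin gene Angpt2 was at 0.82 (SE 0.37), and the Wnt target genes Notum and Tnfrsf19 were at −2.19 (SE 0.67) and −1.39 (SE 0.51).

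**Figure D3:**
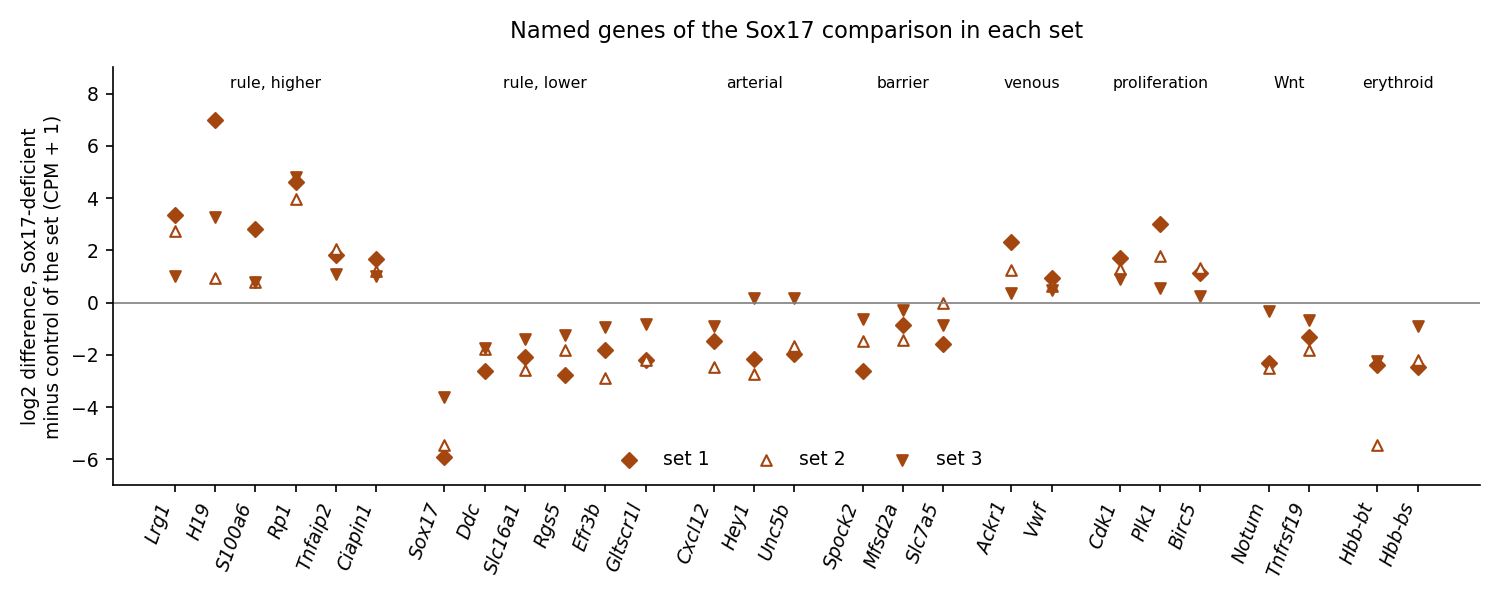
Differences of named genes between the Sox17-deficient and control library of each set, on the log2(CPM + 1) scale, 1 point per set. Slc16a1 lies between −2.60 and −1.41 and Lrg1 between 1.03 and 3.36 over the 3 sets.

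The difference of the effects asked which genes and lists responded differently to loss of Sox7 and loss of Sox17. Pan-endothelial, tip cell, venous, basement membrane and proliferation lists were lower after Sox7 loss relative to Sox17 loss, and the macrophage list was higher. In camera these 6 of 36 lists passed. With an estimated correlation 0 passed (lowest adjusted p = 0.445), and fry gave 0 as well. The replicate block gave 12, all 6 among them. The 6 lists added by the block were pericyte (0.000292), erythroid (0.00625), antigen presentation (0.0231), neutrophil (0.0234) and astrocyte genes (0.033) as higher and immediate early genes (0.0157) as lower. With the block and an estimated correlation these were at an adjusted p of 0.512 to 0.601, and 0 lists passed. All of them but the neutrophil list also passed, without the block, when at least 1 of the 10 libraries was left out. The count was 10 without Sox7-deficient 2 and also without Sox17 control 3.

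Venous genes had the largest median difference among the lower lists, −1.23 (adjusted p = 0.000349; adjusted p = 0.514 with an estimated correlation). By set, the venous mean was −0.715 and −0.495 in Sox7 sets 1 and 2. It was 1.48, 0.771 and 0.0316 in Sox17 sets 1, 2 and 3. Basement membrane genes were at −0.83 (adjusted p = 0.000349; adjusted p = 0.514 with an estimated correlation) and tip cell genes at −0.74 (0.000842; adjusted p = 0.445 with an estimated correlation). Proliferation genes were at −0.95 (0.00572), pan-endothelial genes at −0.55 (0.00408) and macrophage genes at 1.66 (0.037), each at adjusted p = 0.614 with an estimated correlation. The venous call held without any of the 10 libraries. Without Sox7-deficient 1 the basement membrane, pan-endothelial and tip cell lists were at 0.177, 0.644 and 0.154, with means of −0.494, −0.15 and −0.666 against −0.73, −0.47 and −0.669 with all libraries, and the macrophage list reversed to −1.15. The proliferation list had a mean of −0.925. Its call was lost without Sox7 control 1 (mean −0.191), without Sox7-deficient 2 (where the mean turned to 0.239) and without Sox17 control 2 (0.0537, mean −0.794). The macrophage list had a mean of 2.67 and was at 0.0617 without Sox7 control 2 (mean 1.62) and 0.442 without Sox17 control 2 (mean 1.56). It was at 0.263 without Sox17-deficient 1 (mean 1.90) and 0.0613 without Sox17-deficient 3 (mean 2.76). Arterial (0.977), blood-brain barrier (0.959), Notch (0.228) and ribosomal protein lists (0.201) did not pass for the difference. The barrier list passed as higher without Sox7-deficient 1 (mean 0.674, adjusted p = 0.0124) and as lower without Sox7-deficient 2 (−0.41, 0.00247). The ribosomal list passed as lower without Sox7 control 1 (0.0398) or Sox7-deficient 1 (0.0347).

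No gene passed for the difference with edgeR (0 of 13040), with 374 at an unadjusted p under 0.05 against 652 from chance alone. DESeq2 called 15, limma-voom 0 and edgeR without a filter 58. The replicate block gave 3 genes, Sox17 (log2 5.12, adjusted p = 0.047), Ms4a6c (9.69, adjusted p = 0.000245) and Cd72 (adjusted p = 0.00171), of which Cd72 was chosen after its values were seen. Ms4a6c and Cd72 were at 531 and 367 CPM in Sox7-deficient 1, the library with high macrophage transcripts, and at 8.23 and 0 CPM in Sox7-deficient 2, while Cd68 was at 89.8 and 2.92 CPM. In the Sox7 comparison without Sox7-deficient 1 Ms4a6c was at −0.52. Without Sox7-deficient 1 the count was 9, including Sox17 (5.83, adjusted p = 0.0302). Without the block the difference was 5.10 (SE 1.14) for Sox17, −5.17 (SE 1.24) for Sox7, 8.84 (SE 2.87) for Cd68 and 4.48 (SE 1.39) for the lysosome-positioning gene Kxd1. It was −2.75 (SE 0.71) for the potassium channel gene Kcnj2 and −6.10 (SE 1.78) for Aqp1. Rp1, Spint1, Lst1 and Mid2 also met the rule, but each had a group with all libraries at 0 and no fold is given.

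**Figure D4:**
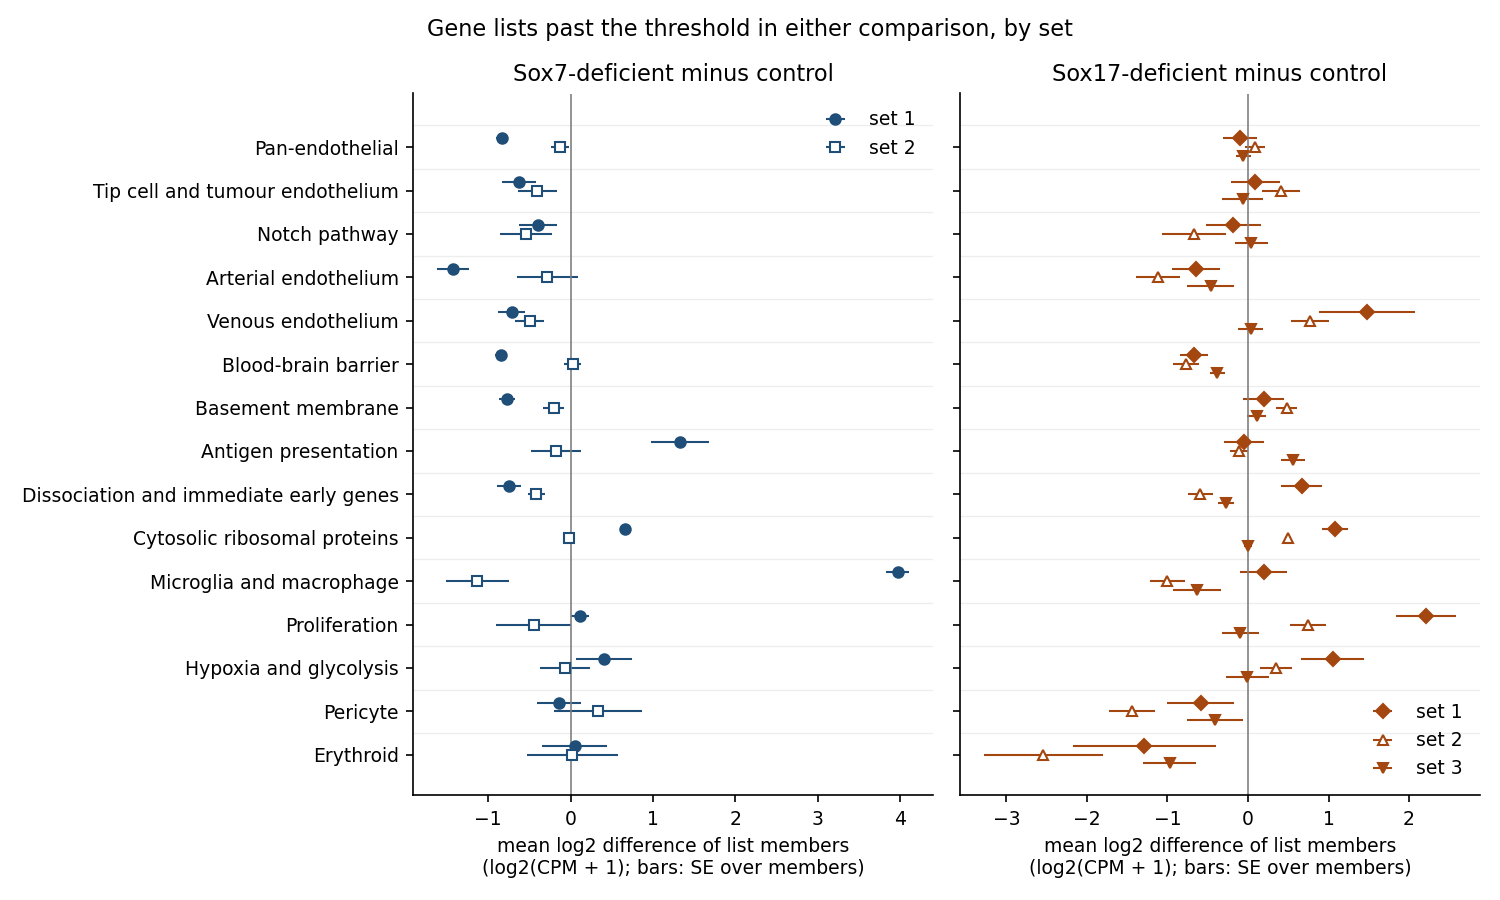
Mean log2(CPM + 1) difference of deficient minus control over the members of 15 gene lists, for each of the 5 sets, with bars of 1 standard error over members. Macrophage genes are at 3.97 in Sox7 set 1 and −1.13 in Sox7 set 2, while barrier and arterial genes are below 0 in all 3 Sox17 sets.

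Fold changes of the comparisons were nearly unrelated across genes. Over 13040 genes Pearson's r was −0.057 and Spearman's rho −0.012, as a description, since genes are not independent replicates and the arms share no control. Without Sox7 control 1 r was −0.103, without Sox7-deficient 1 it was 0.0542 and without Sox17 control 2 it was 0.0074. At an unadjusted p under 0.05, 2 genes were higher in both comparisons (Chl1 and Rn4.5s; 0.834 expected) and 1 was lower in both (Plat; 2.33 expected). Another 3 were higher after Sox7 loss and lower after Sox17 loss (Cd68, Clip3 and Hes5; 3.07 expected), and 2 the reverse (Gpr17 and Kcnj2; 0.631 expected). These genes were chosen after their values were seen, and no overlap passed Fisher's exact test (lowest adjusted p = 0.406).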

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

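The tests of explanations in this part were chosen only after the results were seen, and the test of the difference itself was not. The test of the Sox7 effect minus the Sox17 effect singled out 6 gene lists, with camera adjusted p-values that were all lost with an estimated correlation (lowest adjusted p = 0.445). Venous genes differed by a mean log2 of −1.17 (adjusted p = 0.000349), from −0.63 after Sox7 loss and 0.545 after Sox17 loss, and kept the call without any of the 10 libraries. In Sox17 set 3, however, the venous mean was only 0.0316 (SE 0.156). Basement membrane genes differed by −0.73 (adjusted p = 0.000349), from −0.49 and 0.24, and by −0.494 without Sox7-deficient 1 (adjusted p = 0.177). Tip cell genes differed by −0.67 (adjusted p = 0.000842), from −0.52 and 0.15, and by −0.666 without that library (adjusted p = 0.154). Proliferation genes differed by −0.925 (adjusted p = 0.00572), from −0.19 and 0.73, but by 0.239 without Sox7-deficient 2 (adjusted p = 0.346). Pan-endothelial genes differed by −0.47 (adjusted p = 0.00408), from −0.48 and −0.00883, but by −0.15 without Sox7-deficient 1 (adjusted p = 0.644). Macrophage genes differed by 2.67 (adjusted p = 0.037), from 1.16 and −1.51, and by −1.15 without Sox7-deficient 1.

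In Sox7-deficient 1 all 17 tested macrophage genes exceeded the control of its set, with C1qa at 9170 against 512 CPM and Ctss at 5040 against 294 CPM, while 6 lists of endothelial genes besides the pan-endothelial list were lower in the fit. A lower endothelial share that raises all other cell types alike is argued against by the means in set 1. These were 3.97 for macrophage, −0.142 for pericyte, 0.135 for smooth muscle, 0.435 for astrocyte and 1.06 for oligodendrocyte genes. Macrophage genes exceeded pericyte genes by 13.6 standard errors, but over members of a single library pair, which measures no spread between samples. A change that goes with Sox7 loss in both sets is argued against by the macrophage mean of −1.13 in set 2. RNA from macrophages in that library may account for the rise. It was tested with 23 myeloid and leukocyte genes outside all lists, written down after the pattern was seen. All 23 were higher there by more than 1 on the log2 scale (Laptm5 at 2210 against 143 CPM). T and NK cell genes (mean 1.85, SE 0.568) and neutrophil genes (1.06, SE 0.827) were higher in set 1 as well, so the RNA need not come from macrophages alone. Purification of endothelial cells would be meant to remove such cells, and no member of the macrophage list belongs to another list. One dilution factor may also account for part of the endothelial decrease in set 1, but this is not settled. There 5 lists differed from the pan-endothelial list by a median log2 of 0.142 (−0.0227 to 0.441). They were taken because they had passed as lower in these data, so their agreement has little weight. One factor for all RNA but that of macrophages would lower other cell types alike. Pericyte genes were at −0.142 (SE 0.267) and smooth muscle genes at 0.135 (SE 0.216), against −0.836 (SE 0.0637) for the pan-endothelial list. Arterial genes differed from it by −0.595 (SE 0.204) in set 1 and −0.153 (SE 0.386) in set 2. These standard errors are over members of a single library pair, so a further arterial decrease beyond dilution stays open. A true difference in the macrophages of that tumour and an effect of Sox7 loss on endothelial genes stay open, untested.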

How the results depend on the processing

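Among the alternatives, the fits without Rn45s, the replicate block with limma-voom or DESeq2, and the lists without shared members and SoxF genes were chosen only after the data were seen. Counts of genes are given for the Sox7 comparison, the Sox17 comparison and the difference of effects, each 0 with edgeR. They stayed at 0 with limma-voom, other size factors, total counts, the stricter filter and without Rn45s. DESeq2 gave 3, 29 and 15, and edgeR without a low-count filter 58, 30 and 58. The replicate block gave 1, 6 and 3 over all libraries, and 0 and 1 in fits of only the compared groups. The replicate block with DESeq2 gave 19, 88 and 40, and with limma-voom 9, 0 and 0. Leaving out 1 library gave 0 to 14, 0 to 1 and 0 to 9. In those fits a group left with 1 library is assumed to vary like the others. Gene lists past the threshold numbered 11, 9 and 6. They became 0, 0 and 0 with an estimated correlation and with fry, 12, 15 and 12 with the replicate block, and 2 to 16, 6 to 11 and 5 to 10 without 1 library. In camera and in edgeR over all libraries, the block ended no call of a list or named gene, and besides the calls given with the results above it changed no other. With total counts the immediate early (0.0324) and erythroid lists (0.0373) also passed for the difference of effects. Without shared members and SoxF genes 22 of the 26 list calls were kept.

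Sox7 in its own comparison stayed lower throughout. Adjusted over the list alone, it no longer passed with limma-voom (−3.94, adjusted p = 0.329), in a fit of only the Sox7 libraries (−4.54, 0.195), there with the replicate block (−4.23, 0.238), or with the replicate block and limma-voom (−4.15, 0.0922). Sox7 ranged from −5.20 to −3.25 and Sox17 from −6.36 to −4.78 without 1 library, all past the threshold over the list alone. The correlation of fold changes ranged from −0.103 to 0.0542.

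Some directions reversed when 1 library was left out. In the Sox7 comparison the lowest and highest list means were −0.716 and 1.59 for antigen presentation, −0.957 and 0.109 for the blood-brain barrier and −2.70 and 5.18 for macrophages, and −1.15 and 6.71 for macrophages in the difference of effects. The mean of proliferation genes in the difference of effects turned from −0.925 to 0.239 without Sox7-deficient 2, while the test stayed downward. For genes they were −0.40 and 3.02 for Cd74, −1.22 and 5.37 for Csf1r, −0.52 and 11.33 for Ms4a6c, −1.97 and 0.48 for Slc2a1, −1.705 and 0.59 for Sox17, and −2.53 and 1.42 for Sox18. In the Sox17 comparison they were −0.34 and 0.064 for Kdr, −0.14 and 0.92 for Sox18 and −0.015 and 1.16 for Sox7. Of 94 named-gene results, all 94 kept their side of the threshold and direction with limma-voom, other size factors, total counts and the stricter filter, whereas 7 newly passed with DESeq2 and 22 without a filter. With the replicate block 6 newly passed with edgeR over all libraries, 1 with limma-voom (Csf1r after Sox7 loss, 0.0276) and 22 with DESeq2. Those 22 included, after Sox17 loss, Ackr1 (0.0379), Cxcl12 (0.0139), Efr3b (0.0313), Tnfaip2 (0.0214), Hbb-bs (0.0425) and Hbb-bt (0.00271), and Cd68 for the difference of effects (0.0134). The cause was not tested for these changes, except that leaving out a library leaves fewer samples. Depth may have limited the detection of low genes, since 1 Sox17 control had 2085020 counts, but this was not tested. Depth may also enter the rise of proliferation, ribosomal, hypoxia and venous lists after Sox17 loss. Those lists rose only in sets whose deficient library was deeper than its control, and this was not tested either.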

Other observations

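The tests of explanations in this part were chosen only after the results were seen, except the photoreceptor transcripts and the splits of the samples. Several processes relevant to tumour vessels did not pass in either comparison with all libraries, with camera adjusted p given for Sox7 loss and then Sox17 loss. These were VEGF signalling (0.205 and 0.944), shear-responsive genes (0.133 and 0.159), endothelial-to-mesenchymal transition (0.771 and 0.764), leukocyte adhesion (0.467 and 0.663), interferon response (0.71 and 0.659) and cholesterol synthesis (0.71 and 0.659). The p53 response (0.718 and 0.751) and the unfolded protein response (0.71 and 0.673) did not pass either. The Wnt/beta-catenin (0.71 and 0.165) and TGF-beta lists (0.71 and 0.137) passed in the Sox17 comparison with the replicate block, as did the SoxF family (0.165 and 0.406) in the Sox7 comparison. With the block and an estimated correlation these were at adjusted p = 0.538, 0.538 and 0.457. The SoxF list holds the deleted gene itself in either comparison. Without Sox7-deficient 2 the shear-responsive (0.000707), Wnt (0.0212) and SoxF lists (0.00426) passed as lower after Sox7 loss, and without Sox17-deficient 1 (0.0492) or Sox17 control 3 (0.004) the Wnt list did so after Sox17 loss. Lower as well were proliferation genes after Sox7 loss without Sox7 control 2 (0.0106) and immediate early genes after Sox17 loss without Sox17 control 1 (0.00814). After Sox17 loss the flow-responsive factor genes Klf2 and Klf4 were at log2 −0.97 (SE 0.46) and −0.74 (SE 0.41). The phosphatase gene Ptprb was at −1.08 (SE 0.45) and the VEGF receptor genes Flt1 and Kdr at −0.81 (SE 0.42) and −0.17 (SE 0.39), each at edgeR adjusted p = 1.

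Markers of other cells mostly did not pass. Adjusted p for Sox7 and Sox17 loss was 0.71 and 0.695 for lymphatic endothelium, 0.0623 and 0.798 for smooth muscle, 0.71 and 0.738 for fibroblasts, 0.866 and 0.406 for neutrophils and 0.776 and 0.432 for T and NK cells. It was 0.643 and 0.165 for astrocytes, 0.141 and 0.746 for oligodendrocytes, 0.252 and 0.391 for neurons, 0.776 and 0.19 for glioma and neural progenitors and 0.705 and 0.945 for sex-linked genes. Leaving out 1 library changed some of these. After Sox7 loss neutrophil (0.0407) and T and NK cell lists (0.00164) passed as higher without Sox7-deficient 2, as did astrocytes without Sox7-deficient 1 (0.0351) or Sox7 control 2 (0.00446). The choroid plexus list, which could be tested without Sox7 control 1, passed there as lower (0.00445). After Sox17 loss the progenitor list passed as lower without Sox17-deficient 1 (0.0492) or Sox17 control 3 (0.0324). Of its members Prom1 was at −1.60 (SE 0.47) after Sox17 loss and passed adjusted over the list alone. Median, mean and test differed in sign for some lists that did not pass. In the Sox7 comparison TGF-beta genes had a median of −0.19, a mean of 0.21 and an upward test, Wnt genes −0.33, 0.0051 and a downward test, and transition genes 0.12, −0.22 and a downward test. The SoxF family in the Sox17 comparison had a median of 0.155 and a mean of −1.71, set by Sox17. Lymphatic genes in the Sox7 comparison differed in sign as well (0.42, −0.091 and downward). So did pan-endothelial (−0.00742, −0.00883 and upward), VEGF, transition, leukocyte adhesion, cholesterol, unfolded protein and sex-linked lists in the Sox17 comparison. The SoxF, Notch (−0.47, 0.31 and downward), shear, transition, unfolded protein, lymphatic and fibroblast lists differed in sign for the difference of effects. No list that passed in a comparison showed such a difference.

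Arterial and blood-brain barrier genes fell in Sox17-deficient cells while pan-endothelial genes had a mean of −0.0788 (SE 0.119) over edgeR fold changes, and of −0.00883 over the voom values of the list test. A lower share of endothelial RNA would lower the pan-endothelial list alike. By set its means were −0.0982, 0.0893 and −0.0585, against −0.642, −1.12 and −0.463 for arterial and −0.67, −0.767 and −0.38 for barrier genes. These values argue against a lower share as the whole source. The pan-endothelial mean exceeded the nearer list by 2.54 standard errors, but over members, which measures no spread between samples. A single aberrant library as the sole source is argued against, since both lists were lower in each set. The highest adjusted p without any library was 0.0294 at the preset correlation, and only Sox17 libraries enter this contrast. Members that vary together between samples stay open, since the adjusted p was 0.375 with the correlation estimated, but that run also recovered only 1 of 3 truly shifted lists in simulated data of this comparison. An effect of Sox17 loss stays open as a hypothesis.

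The 6 Sox17 libraries allow 10 splits into groups of 3, too few for a share under 0.05. As many genes as the real 0 passed in 10 of the 10 splits (highest other 1), 4 splits had as many genes at an unadjusted p under 0.05 as the real 459 (highest other 636), and 2 had as many lists as the real 9 (highest other 11). The split that gave 636 and 11 set both libraries of set 1 with control 2 against both of set 3 with deficient 2. Other splits that kept a set together gave 3, 3, 2, 6 and 1 lists. Those that part all 3 sets gave 8, 1 and 1 lists besides the real 9. A structure between sets is therefore possible but not settled by these splits. With the replicate block the real comparison gave 6 genes. Among the 4 splits that part all 3 sets, 1 gave as many with the block, the real one, with 0 as the highest other.

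Rp1 was present in all 3 Sox17-deficient libraries and almost absent elsewhere. A rise of all genes around the Sox17 locus is argued against by 5 tested neighbours (Mrpl15, Lypla1, Tcea1, Rgs20 and Atp6v1h), with a median log2 fold change of 0.409. All 5 values were above 0, with SEs from 0.678 to 2.61. These neighbours lie on the other side of Sox17 from Rp1, so a rise confined to the Rp1 side was not tested. RNA from photoreceptors is argued against, since 0 of 8 photoreceptor transcripts had 10 or more counts in the deficient libraries. Transcription that runs on from the recombined Sox17 allele into Rp1, which lies downstream on the same strand, may be the source, but this and an effect of Sox17 loss itself cannot be told apart, because the allele and the loss go together in every library and the highest Rp1 count in the Sox7 arm was 6. At the Sox7 locus, Rp1l1, a related gene 41773 bp away, had 0 counts in all 10 libraries.

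Some further values concern the libraries rather than a single contrast. The Xist count was 3895 in Sox7 control 1 and 3797 in Sox7-deficient 1, where Ddx3y had 632 and 411 counts, and the other 8 libraries had 0 to 14 counts of Xist and 487 to 5677 of Ddx3y. Xist was thus high in both libraries of Sox7 set 1, and at 0 and 8 counts in control and deficient of Sox7 set 2. A difference in sex between these sets may add to the spread within the Sox7 groups. It may also enter the Sox7 fits without 1 library. This was not tested. The 1183 microRNA symbols listed only in the Sox17 files took 0.067% to 0.13% of the counts.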
